A study of Mus musculus with 4 samples.

How the data were processed

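Total RNA of lactating mammary gland from Swiss albino mice was measured on 4 arrays of a single Agilent 8x60k slide, 2 labelled PBS and 2 labelled E. coli. Groups were taken from the sample titles, and the last digit of each title's replicate label served as the replicate number. The labels do not say that the arrays of a group are separate animals, so p-values of single genes measure only the spread between these arrays.

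The authors deposited Agilent Feature Extraction scanner output for each array, whose spot brightness values are intensity on a linear scale. Per the file headers, Feature Extraction 10.5.1.1 made them, including the processed signal after its background subtraction, the background median, and flags for outlier spots, saturation and signal well above background. RNA was isolated with RNeasy columns and amplified to Cy3-labelled complementary RNA, per the labels' protocols. The authors also deposited a table of log2 values for the same arrays. Set against the scanner values by probe name (61307 probes matched), it held log2 signal scaled to each array's 75th percentile and then centred on each probe's median over the 4 arrays; 99.97% of probes had all between-array differences within 0.05 of those computed here. Its column medians were -0.06 for PBS replicate 1, 0.39 for PBS replicate 2, -0.08 for E. coli replicate 1 and -0.02 for E. coli replicate 2. How the authors treated flagged spots in that table is not given in the sources used here, nor is a genome build, so no genome positions are given.

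Each array has 62976 spots, of which 61657 are not controls, for 61307 probes: 40628 for genes or transcripts with a RefSeq, GenBank or similar name and 20679 for NONCODE transcripts, which are counted but not named. Accessions of 28136 probes were found in the RefSeq table of assembly GRCm38.p6, which was used for names only. It replaced 3897 symbols, and a further 1406 were updated through a unique synonym; other names are those of the array design. The depth of an array is its signal over background: 58.5%, 47.7%, 61.2% and 58.0% of spots were well above background on PBS replicate 1, PBS replicate 2, E. coli replicate 1 and E. coli replicate 2, with 573, 124, 584 and 489 saturated spots and 125, 82, 45 and 40 outlier spots. The number of arrays limits the precision.

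The value analysed was log2 of the processed signal minus the array's 75th percentile over non-control probes. Control spots and outlier spots were left out, saturated spots were kept, spots of a probe were averaged, and 262 probes with no usable spot on an array were left out. A probe was tested if it was well above background on both arrays of at least 1 group. A gene was represented by its brightest probe over all 4 arrays; 5855 genes had several tested probes, and in 10 of these some probes were called higher and others lower. Groups were compared with limma (lmFit and eBayes, version 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment over the 27188 genes and transcripts tested, at an adjusted p of 0.05; a further count required a change of at least 2-fold. The residual degrees of freedom were 2 and the prior added 2.43. The ± after a log2 change is its standard error from that fit.

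Where a gene was not well above background, or was saturated, on both arrays of a group, its change is given as "at least N-fold": the brighter group's mean against the dimmer group's mean, where each dim array counts as the higher of the probe's own signal and the lowest signal well above background on that array. Genes saturated in both groups have no fold (83 genes).

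The gene lists (38, each with its members) were fixed before the data were examined, as were the groups, the test, the thresholds, the rule for named genes and all alternatives other than the 2 named below. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. At that setting camera compares a list's genes with all other genes, so its p-values measure spread across genes, not arrays. Camera with an estimated correlation, which has only the 2 residual degrees of freedom of the arrays, and fry were alternatives. The text names the 10 largest rises and 10 largest falls among called genes above background on all arrays with groups that do not overlap, the 5 largest bounds in each direction, 18 genes fixed in advance, and for each list up to 4 called members with the largest change and up to 2 called members that moved against the list's mean. One list member chosen by this rule, Oas3, is left out of the text because its brightest probe and its other probe differ in being above background with PBS. A few other genes that the rule selects are not reported here.

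The alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, scaling to the median, the 75th percentile over probes above background on all arrays, no filter on dim probes, a filter requiring all 4 arrays, saturated probes left out, the mean over a gene's probes, every probe counted, eBayes with trend and robust options, the replicate number as a block, each array left out in turn, the deposited log2 table, and an adjusted p of 0.01. The normexp offset of 50 exceeds the median processed signal of every array (19.4 to 35.0). Smaller folds for dim genes are therefore built into that alternative, and it cannot test their size. Leaving out the NONCODE probes and cyclic loess normalization were added after the arrays had been seen. All arrays share a slide and a scan, so no block for these applied.

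The fit was tested on simulated data made from these arrays' means and spread for the same 27188 genes (20 simulations). With 200 changed genes, it recovered 0% of 2-fold, 13.0% of 4-fold, 63.7% of 8-fold and 82.9% of 16-fold changes, and 5.46% of calls were false. With 7570 changed genes, it recovered 59.2%, 92.2%, 97.0% and 98.6%, and 3.58% of calls were false. Lists were simulated only with 200 changed genes, not with 7570. There, 0 of 740 tests of unmoved lists were called, and a list moved by 1 log2 unit was found in 20 of 20. The simulated genes varied independently of each other, with the same spread in both groups and variances drawn from limma's own fitted prior. A share of false calls near the threshold is thus built in and is not an error rate for the real calls. In the real data the median SD was 0.236 between the PBS arrays and 0.107 between the E. coli arrays. Because the simulated genes were independent, the list result cannot show how often camera calls falsely where genes vary together. The real milk protein list is a case in point (estimated correlation 0.264). Tables and figures were made with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.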

Results

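Transcript levels were measured in the abdominal mammary gland of lactating Swiss albino mice at day 7 after birth of the litter. The study asked how gene expression in the gland differs 24 h after infection with an Escherichia coli strain obtained from cow milk. RNA from glands given PBS (2 arrays) and from infected glands (2 arrays) was labelled with Cy3 and hybridised to a 1-colour Agilent mouse array. The labels do not say whether the 2 arrays of a group came from separate animals. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Those of camera at the preset correlation set a list's genes against other genes and treat genes as nearly independent. The 75th percentile of the processed signal was 472 on PBS replicate 1, 250 on PBS replicate 2, 504 on E. coli replicate 1 and 469 on E. coli replicate 2. PBS replicate 2 was the dimmest array, with 47.7% of spots well above background against 58.5%, 61.2% and 58.0% on PBS replicate 1, E. coli replicate 1 and E. coli replicate 2. Across genes, which are not independent replicates, the E. coli arrays correlated at r = 0.993 and the PBS arrays at r = 0.978, and arrays of different groups at r = 0.922 to 0.935.

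After 24 h of infection, transcripts of neutrophils, phagocytes, cytokines, chemokines and interferon responses were higher, and transcripts for milk proteins, milk lipid synthesis and the secretory pathway were lower, while skeletal muscle transcripts were also higher (list mean 2.47). No gene list passed with a correlation estimated from these arrays (lowest adjusted p = 0.206), and of the 3 lower groups 8 of 17, 13 of 30 and 9 of 22 genes passed, of which 1, 0 and 1 did so with either E. coli array left out. The list test with an estimated correlation rests on only 2 residual degrees of freedom. It had little power, so its failures do not show that the lists did not change. Among genes well above background on all arrays, the largest rise was that of Acod1, which makes the antimicrobial metabolite itaconate in activated macrophages. Acod1 rose by 9.89 ± 0.17 on the log2 scale (SE, n = 2 and 2, 950-fold, limma adjusted p = 0.00149). It was followed by the C-type lectin Clec4d (9.09 ± 0.39, 546-fold), the formyl peptide receptor Fpr2 (8.34 ± 0.19, 323-fold), the pyrin gene Mefv (8.30 ± 0.25, 316-fold) and the interleukin-1 receptor antagonist Il1rn (8.25 ± 0.28, 304-fold). Cstdc6, Fpr1, the granulocyte colony-stimulating factor receptor Csf3r, coagulation factor F10 and Il1b completed the 10 largest rises, at 229-fold, 190-fold, 180-fold, 131-fold and 107-fold. The largest fall was that of Cck, which encodes cholecystokinin, at -6.04 ± 0.17 (65.7-fold lower, adjusted p = 0.00149). The pancreatic-type ribonuclease Rnase1 was 48.0-fold lower (-5.58 ± 0.23), Ccdc74a 46.4-fold, the microfibril protein Mfap4 32.3-fold and the vitamin D 24-hydroxylase Cyp24a1 28.8-fold. Vmn1r237, Gsta3, the stearoyl-CoA desaturase Scd3, Lrrc15 and Wdr64 fell by 20.5-fold, 19.6-fold, 16.7-fold, 16.7-fold and 16.4-fold. The adjusted p of these 10 falls lay between 0.00149 and 0.00448. Normexp background correction gave smaller rises for Acod1 (361-fold), Clec4d (220-fold), Fpr2 (133-fold), Mefv (127-fold), Il1rn (150-fold), Fpr1 (97.4-fold), Csf3r (70.7-fold) and F10 (65.6-fold). It also gave smaller falls for Cck (34.7-fold), Mfap4 (8.47-fold), Cyp24a1 (16.2-fold), Vmn1r237 (10.2-fold), Lrrc15 (5.94-fold) and Wdr64 (7.76-fold). With the mean over its probes, Acod1 was 548-fold and Il1rn 124-fold higher.

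Some genes were well above background in only a single group, so that their change has only a lower bound. The macrophage-inducible lectin Clec4e was at least 1287-fold higher after E. coli, the stefin Stfa2l1 at least 751-fold, Cstdc4 at least 708-fold, the neutrophil collagenase Mmp8 at least 229-fold and Slfn4 at least 217-fold. In the other direction, the brown fat uncoupling protein Ucp1 was at least 46.2-fold lower, the cartilage intermediate layer protein Cilp at least 32.6-fold, the keratin Krt78 at least 26.2-fold, the pseudogene Nsa2-ps2 at least 18.35-fold and the cytochrome Cyp1a1 at least 16.1-fold. Each of these 10 genes passed the limma test. The bounds depend on the treatment of background. After normexp, whose offset of 50 shrinks the folds of dim genes by construction, the estimates for all 10 were smaller than the bounds. The rises were 223-fold for Clec4e, 162-fold for Stfa2l1, 147-fold for Cstdc4, 37.1-fold for Mmp8 and 49.2-fold for Slfn4. The falls were 9.48-fold for Ucp1, 7.93-fold for Cilp, 6.55-fold for Krt78, 4.64-fold for Nsa2-ps2 and 4.46-fold for Cyp1a1. Ucp1 was also under its bound with the mean over its probes (15.6-fold lower), and Mmp8 without PBS replicate 1 (159-fold higher).

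Of 27188 genes and transcripts tested with limma, 7570 passed an adjusted p of 0.05, 3766 higher and 3804 lower after E. coli, and 5749 of them changed at least 2-fold (3189 higher, 2560 lower). For every gene that passed, both arrays of the higher group lay above both arrays of the lower group, a separation seen in 70.9% of all genes tested. The share would be 33.3% if all 4 arrays were exchangeable. Arrays of a group that are technical repeats would separate more often without infection, so the 2 shares do not measure its effect. Transcripts of annotated genes were called higher in 2443 cases and lower in 3009, and non-coding transcripts of the NONCODE collection higher in 1323 and lower in 795. Of the calls, 676 genes that rose were not well above background on either PBS array, and 84 that fell were not on either E. coli array. The median SE of a log2 difference was 0.22. Without the filter on dim probes, only 123 of 49656 genes and transcripts passed (113 higher, 10 lower). In that setting 139 of the 187 named genes that passed lost their call. The notes on single genes below do not repeat it. The number of calls depended on which arrays set the spread: without an E. coli array it was 1118 (without replicate 1) or 926 (without replicate 2), and without a PBS array 13544 (without replicate 1) or 9762 (without replicate 2). The split between directions depended on the scaling, with 49.7% of calls higher under the 75th percentile and 60.9% under cyclic loess, where the median change of all genes was 0.05 in place of -0.10.

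**Figure D1:**
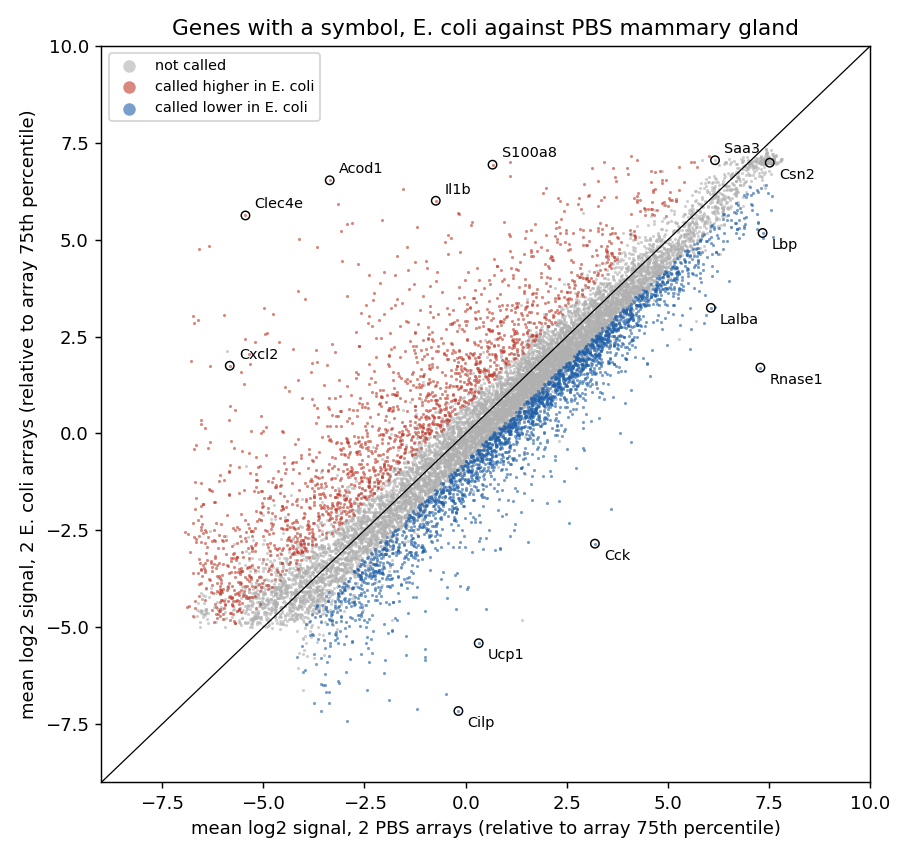
Mean log2 signal of each gene with a symbol on the 2 E. coli arrays (vertical axis) against the 2 PBS arrays (horizontal axis), both relative to the array's 75th percentile; red points were called higher, blue points lower and grey points neither. Acod1 and Il1b lie far above the diagonal of equal signal (950-fold and 107-fold) and Cck far below it (65.7-fold lower), and at the bright end saturation compresses genes such as Csn2.

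Genes fixed in advance for their known part in coliform mastitis included the receptor complex for bacterial lipopolysaccharide, early cytokines and milk genes. Interleukin-1 beta (Il1b) rose 107-fold and tumour necrosis factor (Tnf) 57.2-fold (5.84 ± 0.37, adjusted p = 0.00326; above background on 1 of 2 PBS arrays). Il6 was at least 43.0-fold higher, the granulocyte growth factor Csf3 at least 39.6-fold and the neutrophil chemokine Cxcl2 at least 87.6-fold, each not well above background with PBS, while Cxcl1 rose 9.86-fold (3.30 ± 0.19). The calprotectin subunit S100a8 rose 77.3-fold with 1 E. coli array saturated, and S100a9, saturated on both E. coli arrays, was at least 59.6-fold higher. After normexp the rises were 16.3-fold for Tnf, and under the bounds for Il6 (8.04-fold), Csf3 (9.17-fold) and Cxcl2 (19.5-fold). Lipopolysaccharide-binding protein (Lbp) was saturated on both PBS arrays and at least 4.48-fold lower after E. coli (adjusted p = 0.006; 0.0563 without E. coli replicate 1 and 0.0596 without E. coli replicate 2). The lipopolysaccharide receptor Tlr4 differed by -0.54 ± 0.19 (adjusted p = 0.0985), the acute phase protein Saa3, saturated on both E. coli arrays, by at least 1.85-fold (adjusted p = 0.103) and lipocalin 2 (Lcn2) by 0.59 ± 0.27 (adjusted p = 0.175), none of which passed. Among milk genes, alpha-lactalbumin (Lalba) fell 7.05-fold (-2.82 ± 0.17, adjusted p = 0.00314), whereas beta-casein (Csn2, -0.53 ± 0.30, adjusted p = 0.246, with saturated arrays in both groups) and fatty acid synthase (Fasn, -0.39 ± 0.23, adjusted p = 0.267) did not pass. Whether these 5 genes passed depended on PBS replicate 1. Without it only the E. coli pair set the spread, and the estimates also lay further from 0. The log2 changes were then -0.67 for Tlr4, 1.29 for Saa3, 0.91 for Lcn2, -0.90 for Csn2 and -0.64 for Fasn. For Csn2 and Saa3 this move cannot be told apart from an effect of saturation. Saa3 also passed the limma test after normexp (adjusted p = 0.045). Cd14, Csn1s1 and Wap were saturated in both groups and have no fold.

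**Figure D2:**
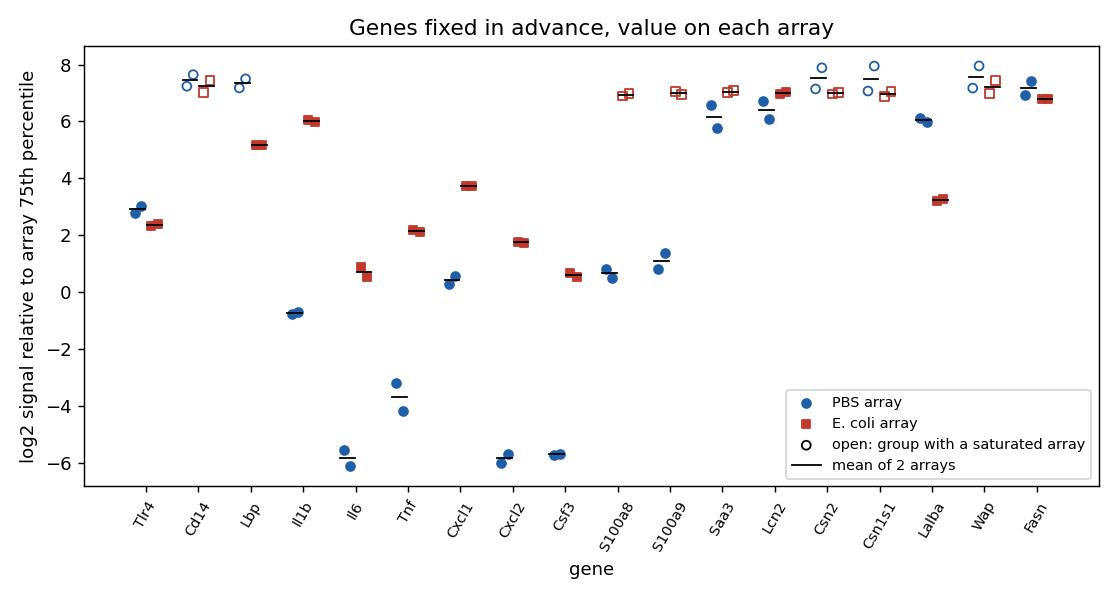
Log2 signal relative to the array's 75th percentile (vertical axis) of the genes fixed in advance (horizontal axis) on each PBS array (circles) and each E. coli array (squares), with the mean of 2 arrays as a bar; open symbols mark a group with a saturated array. Il1b, Il6, Tnf, Cxcl1, Cxcl2 and Csf3 separate between groups by several units, Lalba lies lower after E. coli (-2.82), and Cd14, Csn1s1 and Wap sit at saturation in both groups.

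Each of 38 gene lists was fixed in advance, and 37 had enough members to be tested as a set. With limma's camera at its preset correlation, 26 lists passed, 17 toward higher and 9 toward lower; with the correlation estimated from these 4 arrays, 0 passed (lowest adjusted p = 0.206), with 8 lists at an unadjusted p under 0.05. The rotation test fry called 30 lists in a direction and 37 in either direction, the reference genes among the latter. It asks whether a list's genes change at all, not whether they change more than other genes. With 27.8% of all genes called, its passes say little about a list in particular. They do not settle the lists that camera with an estimated correlation could not. No list that passed turned its mean direction under any other scaling.

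Neutrophil markers rose together. Of 24 tested, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a mean log2 change of 6.27 (camera adjusted p = 6.54e-19; adjusted p = 0.206 with an estimated correlation). Besides Clec4d and the bounds for Clec4e and Stfa2l1, the amplifying receptor Trem1 was at least 187-fold higher. Phagocytosis and NADPH oxidase genes followed, with 21 of 23 higher and 0 lower (22 and 0 adjusted over the list alone, mean 3.39, camera adjusted p = 2.11e-16; adjusted p = 0.206 with an estimated correlation). They included the kinase Fgr (59.3-fold), the integrin Itgam (39.9-fold), the Fc receptor Fcgr4 (32.9-fold) and the oxidase subunit Ncf4 (19.5-fold). Of 19 leukocyte adhesion and migration genes, 14 rose and 0 fell (15 and 1 adjusted over the list alone, mean 2.48, camera adjusted p = 1.85e-08; adjusted p = 0.23 with an estimated correlation), among them the chemokine receptor Cxcr4 (26.7-fold; above background on 1 of 2 PBS arrays) and Cd44 (15.9-fold). Of 24 monocyte and macrophage markers, 15 rose and 0 fell (17 and 1 adjusted over the list alone, mean 1.97, camera adjusted p = 1.97e-08; adjusted p = 0.257 with an estimated correlation). The scavenger receptors Marco (227-fold; above background on 1 of 2 PBS arrays) and Msr1 (33.9-fold), Clec4n (21.1-fold) and Ms4a6d (15.4-fold) led them. Without E. coli replicate 1 the members that kept their call numbered 20 neutrophil, 21 phagocytosis, 9 adhesion and 9 macrophage genes, and without E. coli replicate 2 they numbered 20, 20, 9 and 8. The neutrophil mean was 5.66 over genes above background on all arrays (15 of the 23 that rose) and 4.59 after normexp, where Trem1 was 38.3-fold higher, under its bound, Fgr 32.1-fold, Itgam 18.9-fold, Cxcr4 9.11-fold, Marco 54.2-fold, Msr1 18.2-fold, and Clec4n by 3.70 on the log2 scale. Itgam was 60.8-fold higher without PBS replicate 1 and 26.2-fold without PBS replicate 2. Skeletal muscle transcripts rose in the same arrays, with a list mean of 2.47.

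Chemokines and cytokines rose as groups. Of 32 chemokines tested, 23 rose and 2 fell (26 and 3 adjusted over the list alone, mean 3.40, camera adjusted p = 4.15e-12; adjusted p = 0.257 with an estimated correlation). Cxcl5 was at least 200-fold higher and Cxcl3 at least 95.2-fold, while Cxcl13, which attracts B cells, rose 561-fold and Ccl3 226-fold, each above background on 1 of 2 PBS arrays. The log2 change of Ccl3, 7.82 in the main analysis, was 8.75 without PBS replicate 1, 6.90 without PBS replicate 2 and 5.40 after normexp. The chemokines that fell were Cxcl14 (3.92-fold) and Ccl27a (1.77-fold), both made constitutively rather than after inflammatory signals. Ccl27a did not pass after normexp background correction (adjusted p = 0.0868), with median scaling (0.0589) or with the replicate block (0.0691). Of 32 cytokines, 21 rose and 0 fell (23 and 0 adjusted over the list alone, mean 2.91, camera adjusted p = 7.01e-12; adjusted p = 0.24 with an estimated correlation), and their median was 1.86 with genes not above background set at their bounds. After normexp the cytokine mean was 1.51, with 15 of the 21 rises kept, and the chemokine mean 2.49, with 20 of 23 kept; Cxcl13 was then 138-fold higher, and Cxcl5 (46.2-fold) and Cxcl3 (23.1-fold) were under their bounds. The chemokine mean was 2.16 over genes above background on all arrays, which hold 14 of the 23 that rose. Of 14 inflammasome genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone, mean 1.79, camera adjusted p = 2.05e-05; adjusted p = 0.206 with an estimated correlation), among them Il18 (7.99-fold), the pore-forming gasdermin Gsdmd (6.49-fold) and the sensor Naip2 (5.81-fold). Of 19 genes of eicosanoid and nitric oxide synthesis, 13 rose and 2 fell (13 and 2 adjusted over the list alone, mean 1.52, camera adjusted p = 2.05e-05; adjusted p = 0.206 with an estimated correlation). The inducible cyclooxygenase Ptgs2 was at least 12.4-fold higher, Pla2g7 23.0-fold, arginase Arg1 13.6-fold and inducible nitric oxide synthase Nos2 at least 3.11-fold, whereas the prostaglandin D synthase Ptgds fell 7.46-fold (above background on 1 of 2 E. coli arrays) and the constitutive cyclooxygenase Ptgs1 2.64-fold. Nos2 lost its call after normexp (adjusted p = 0.294), where Il18 was 4.72-fold, Naip2 3.85-fold and Ptgs2, under its bound, 3.79-fold higher, and Ptgds 2.65-fold lower. With E. coli replicate 1 left out, 16 chemokines, 14 cytokines, 5 inflammasome and 4 eicosanoid genes kept their rise, and with replicate 2 left out, 16, 13, 5 and 4; of the falls, that of 1 eicosanoid gene was kept in either case.

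Interferon-stimulated genes rose as a group. Of 40 tested, 36 rose and 0 fell (37 and 0 adjusted over the list alone, mean 2.27, camera adjusted p = 1.98e-19; adjusted p = 0.206 with an estimated correlation), among them the guanylate-binding proteins Gbp5 (30.9-fold) and Gbp6 (18.0-fold) and the oligoadenylate synthetase-like Oasl1 (12.1-fold). Of 24 NF-kappaB factors and targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone, mean 1.65, camera adjusted p = 9.91e-07; adjusted p = 0.206 with an estimated correlation). Tnfaip2 (34.1-fold), the feedback inhibitor Tnfaip3 (29.8-fold), the kinase Ikbke (18.2-fold) and the inhibitor Nfkbie (11.1-fold) rose, and the kinase regulator Ikbkg fell 2.49-fold. In the list for Toll-like receptors and lipopolysaccharide recognition, 10 of 25 rose, 3 fell and 1 was saturated in both groups (11 and 3 adjusted over the list alone, mean 0.94, camera adjusted p = 0.00815; adjusted p = 0.257 with an estimated correlation). The peptidoglycan recognition protein Pglyrp1 rose 25.4-fold, Tlr13 21.9-fold, Tlr1 17.0-fold and the negative regulator Irak3 7.58-fold, while Lbp and the flagellin receptor Tlr5 (1.89-fold) fell. Tlr5 lost its call with the replicate block (adjusted p = 0.0529) and after normexp (adjusted p = 0.129), where the rise was 10.3-fold for Gbp6, 17.4-fold for Tnfaip2, 9.70-fold for Ikbke, 14.6-fold for Tlr13 and 5.81-fold for Tlr1. The rise was kept without E. coli replicate 1 by 20 interferon-stimulated, 9 NF-kappaB and 6 receptor genes, and without replicate 2 by 19, 9 and 5, and 0 of the falls were kept in either case.

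Acute phase and antimicrobial proteins moved both ways. Of 29 tested, 11 rose, 4 fell and 4 were saturated in both groups (12 and 5 adjusted over the list alone, mean 0.85, camera adjusted p = 0.0222; adjusted p = 0.351 with an estimated correlation), and the list did not pass without PBS replicate 1 (adjusted p = 0.0609). The haem-binding protein Hpx rose 127-fold (above background on 1 of 2 PBS arrays), the chitinase-like Chil3 39.0-fold and the pentraxin Ptx3 34.0-fold, while the fibrinogen chain Fgg fell 23.5-fold (above background on 1 of 2 E. coli arrays) and the whey acidic protein relative Wfdc12 4.93-fold. Of 22 complement genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), and the list did not pass (mean 0.32, camera adjusted p = 0.325). The anaphylatoxin receptors C5ar1 (at least 3.86-fold) and C3ar1 (5.33-fold) and factor B (Cfb, saturated after E. coli, by at least 3.07 on the log2 scale) rose, and the complement regulators Cd55 (4.69-fold) and Cd59a (4.13-fold) fell. C5ar1 lost its call after normexp (adjusted p = 0.227), where Hpx was 26.3-fold and Ptx3 21.5-fold higher and Fgg 4.34-fold lower. Of 30 apoptosis genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone, mean 0.60, camera adjusted p = 0.0146; adjusted p = 0.407 with an estimated correlation). The death-promoting Pmaip1 (14.6-fold) and ligand Tnfsf10 (5.18-fold; above background on 1 of 2 PBS arrays) rose, as did the protective Bcl2a1a (9.16-fold) and Birc3 (5.72-fold), whereas the death-promoting Bbc3 (2.18-fold) and the protective Bcl2 (2.17-fold) fell. Tnfsf10 did not pass with quantile normalization or median scaling (adjusted p = 0.0721 and 0.0683), and its log2 change of 2.37 was 3.20 without PBS replicate 1, 1.55 without PBS replicate 2 and 1.01 after normexp. Nor did Bcl2 pass with the mean over its probes (adjusted p = 0.0641). Leaving out E. coli replicate 1 kept the rise of 5 acute phase, 2 complement and 4 apoptosis genes and the fall of 1, 1 and 0; leaving out replicate 2 kept 5, 2 and 3 rises and 1, 0 and 0 falls.

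Markers of lymphocytes and granulocytes other than neutrophils were also measured in the whole gland. Of 19 T and NK cell markers, 16 rose and 0 fell (17 and 0 adjusted over the list alone, mean 1.99, camera adjusted p = 1.28e-08; adjusted p = 0.206 with an estimated correlation), with granzyme Gzmb 11.7-fold higher, Il7r 9.24-fold and Cd3d 7.73-fold (above background on 1 of 2 PBS arrays). After normexp the T and NK mean was 0.76, 7 of the 16 rises were kept, and Gzmb was 3.81-fold, Il7r 3.84-fold and Cd3d 3.52-fold higher. Only 8 of the 16 were above background on all arrays, where the list mean was 1.88. Among 14 B and plasma cell markers, 8 rose and 2 fell (10 and 3 adjusted over the list alone, mean 1.29, camera adjusted p = 0.0055; adjusted p = 0.257 with an estimated correlation). Their median was 1.75, or 0.95 with genes at their bounds. The B cell surface genes Ms4a1 (at least 14.4-fold), Cd22 (at least 3.35-fold), Fcrla (at least 2.35-fold) and Cd37 (by 2.72 ± 0.23 on the log2 scale) rose, and the plasma cell genes Tnfrsf17 (4.09-fold) and Jchain (1.75-fold) fell. The B cell list did not pass after normexp (mean 0.16, adjusted p = 0.198), where Cd22, Fcrla and Jchain had adjusted p = 0.262, 0.599 and 0.123, Ms4a1 was 3.17-fold higher, under its bound, Cd37 was 3.14-fold higher and Tnfrsf17 2.64-fold lower, nor over genes above background on all arrays (mean 0.05, adjusted p = 0.677). Jchain also did not pass with cyclic loess (adjusted p = 0.0585) or the replicate block (0.0738). Of 10 mast cell and eosinophil markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone, mean 1.36, camera adjusted p = 0.000403; adjusted p = 0.26 with an estimated correlation), with the eosinophil lectin Siglecf at least 11.3-fold higher, Ccr3 4.43-fold (above background on 1 of 2 PBS arrays), Fcer1a at least 2.31-fold and Prg2 2.11-fold. Of these, Ccr3, Fcer1a and Prg2 had adjusted p = 0.0703, 0.819 and 0.848 after normexp, where the list mean was 0.44 and Siglecf was 2.78-fold higher, under its bound. Fcer1a also did not pass with quantile normalization (adjusted p = 0.0792). Over genes above background on all arrays, which hold 2 of the 5 that rose, the mean was 0.58. The list of dendritic cells and MHC class II did not pass (mean 0.19, camera adjusted p = 0.224), with 3 of 14 higher and 1 lower (5 and 2 adjusted over the list alone). In it, Ccr7 was at least 4.52-fold higher, H2-Oa 2.87-fold (above background on 1 of 2 PBS arrays) and Itgax 1.85-fold, and the peptide loader H2-DMb1 fell 11.7-fold. Ccr7 and H2-Oa had adjusted p = 0.252 and 0.644 after normexp, where H2-DMb1 was 7.30-fold lower, and Itgax had adjusted p = 0.0636 with the replicate block. In these lists, 5 T and NK, 2 B cell, 1 mast cell and eosinophil and 0 dendritic cell genes kept their rise without E. coli replicate 1, and 5, 3, 1 and 1 without replicate 2; of the falls, 0 of the B cell list and 1 of the dendritic cell list were kept in either case.

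Skeletal muscle transcripts were higher in both E. coli arrays. Of 15 markers, 14 rose and 1 fell (14 and 1 adjusted over the list alone, mean 2.47, camera adjusted p = 3.16e-09; adjusted p = 0.206 with an estimated correlation). Fast-fibre Actn3 rose 18.7-fold, muscle creatine kinase Ckm 16.2-fold, Mylpf by 3.39 ± 0.18 on the log2 scale and Tnnt3 10.4-fold, and myoglobin (Mb) fell 8.90-fold. With the mean over its probes, Tnnt3 was 3.78-fold higher. Of 9 lymph node stroma genes, 3 rose and 2 fell (5 and 4 adjusted over the list alone), and the list did not pass (mean 1.43, camera adjusted p = 0.24); Cxcl13, lymphotoxin Ltb (42.6-fold) and Pdpn (4.55-fold) rose, and the lymphatic vessel gene Lyve1 (4.27-fold) and the addressin Madcam1 (2.43-fold) fell. Normexp gave a rise of 138-fold for Cxcl13 and 2.13-fold for Pdpn. Only 4 erythroid genes were tested, too few for a set test, and none of the 4 passed. The rise of 9 muscle and 2 lymph node genes was kept without E. coli replicate 1, and of 8 and 2 without replicate 2; the fall of Mb was kept only in the former case, and 0 lymph node falls in either.

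**Figure D3:**
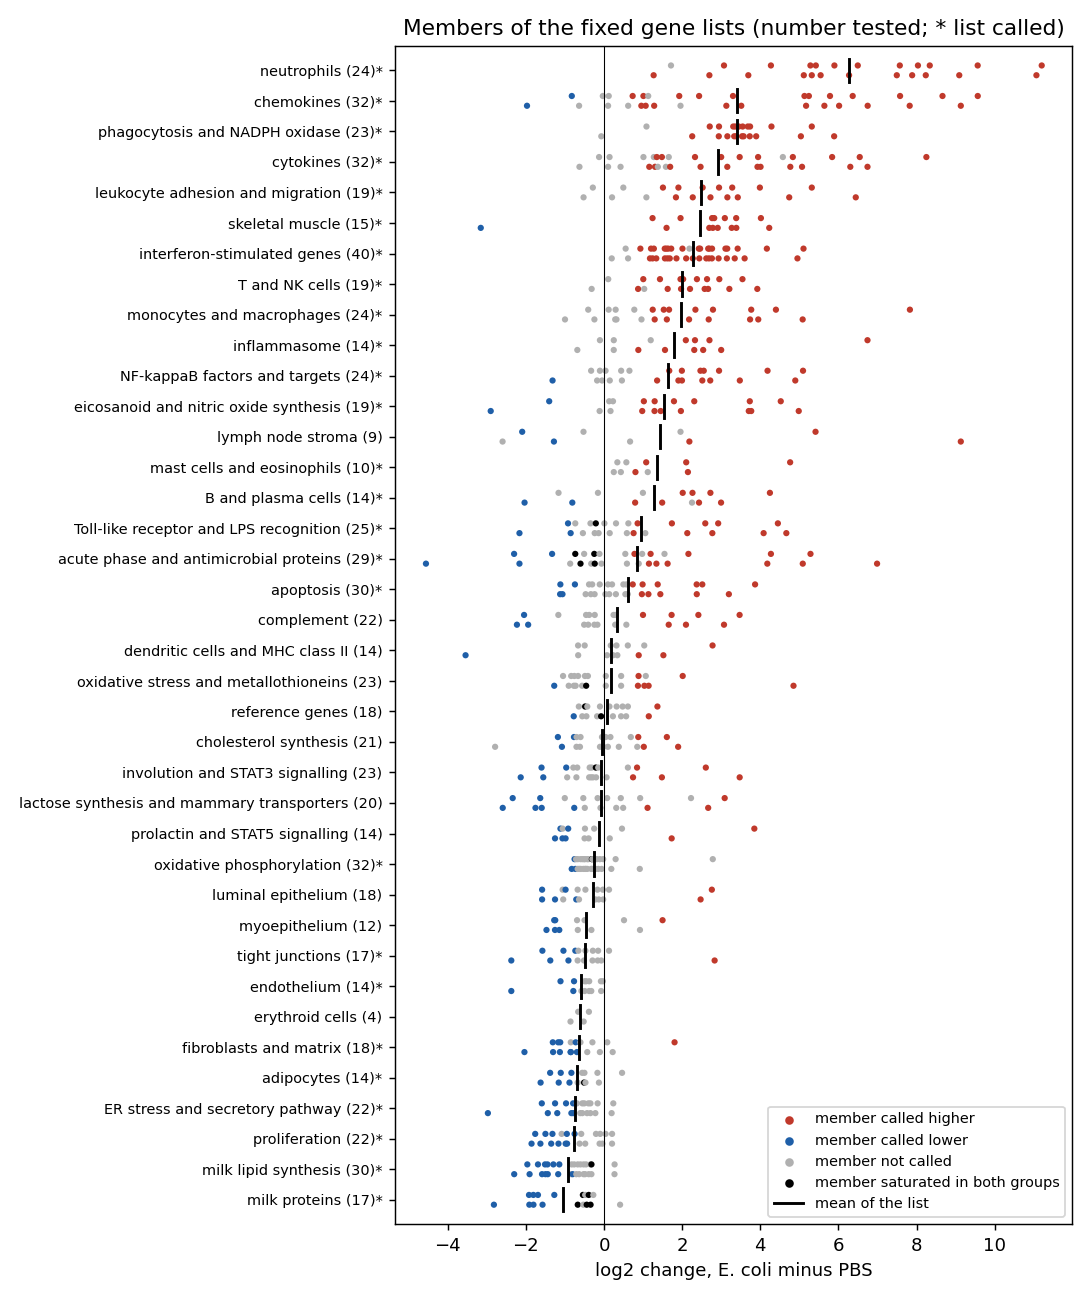
Log2 change, E. coli minus PBS (horizontal axis), of each tested member of the fixed gene lists (vertical axis, with the number tested; an asterisk marks a list that passed camera at the preset correlation); red points were called higher, blue points lower, grey points neither and black points were saturated in both groups, and the bar is the mean. Neutrophil genes had the highest mean (6.27) and milk protein genes the lowest (-1.06).

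Some genes of milk proteins and milk lipid synthesis fell while leukocyte and muscle transcripts rose. Of 17 milk protein genes, 0 rose and 8 fell, 4 did not pass and 5 were saturated in both groups (0 and 8 adjusted over the list alone, mean -1.06, camera adjusted p = 0.000431; adjusted p = 0.351 with an estimated correlation). The median was -0.67, or -1.69 over members with no saturated array. Besides Lalba, the mucin Muc1 fell 3.78-fold, the L-amino acid oxidase Lao1 3.76-fold with 1 PBS array saturated, and kappa-casein Csn3 3.50-fold. Of 30 milk lipid synthesis genes, 0 rose, 13 fell and 1 was saturated in both groups (0 and 16 adjusted over the list alone, mean -0.92, camera adjusted p = 2.58e-06; adjusted p = 0.257 with an estimated correlation), among them the desaturase Scd1 (4.92-fold, 1 PBS array saturated), the fatty acid transporter Cd36 (3.90-fold), Aldoc (3.74-fold) and the lipogenic transcription factor Srebf1 (3.23-fold). Of 22 genes of ER stress and the secretory pathway, 0 rose and 9 fell (0 and 10 adjusted over the list alone, mean -0.74, camera adjusted p = 0.000431; adjusted p = 0.351 with an estimated correlation), with Chac1 7.84-fold lower, Dnajb9 3.01-fold, the secretory regulator Xbp1 2.71-fold and Creld2 2.38-fold. Lactose synthesis and mammary transporters did not pass as a list (mean -0.08, camera adjusted p = 0.58), with 3 of 20 higher and 6 lower (3 and 6 adjusted over the list alone). There the amino acid transporter Slc6a14 (at least 2.57-fold) and the phosphate transporter Slc34a2 (6.35-fold) rose, and the folate receptor Folr1 (6.03-fold) and the calcium pump Atp2c2 (5.05-fold) fell. Slc6a14 had adjusted p = 0.367 after normexp, where Slc34a2 was 4.01-fold higher. Cholesterol synthesis did not pass either (mean -0.05, test direction upward, camera adjusted p = 0.667), with Idi1 (3.05-fold) among the 4 of 21 that rose and Sqle (2.27-fold) and Fdft1 (2.11-fold) among the 3 that fell (6 and 5 adjusted over the list alone). Without E. coli replicate 1 or replicate 2, only 1 milk protein, 0 milk lipid and 1 secretory gene kept their fall, as did 0 lactose and 0 cholesterol genes, and 1 lactose and 0 cholesterol genes kept their rise.

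Hormone signalling and epithelial marker lists did not pass. For prolactin and STAT5 signalling, 2 of 14 rose and 5 fell (2 and 6 adjusted over the list alone, mean -0.13, camera adjusted p = 0.224): the cytokine-signalling inhibitor Socs1 rose 14.4-fold and Igf1r 3.32-fold, and Gata3 fell 2.38-fold and the STAT5 target Cish 2.17-fold. For involution and STAT3 signalling, 5 of 23 rose, 4 fell and 1 was saturated in both groups (6 and 6 adjusted over the list alone, mean -0.08, camera adjusted p = 0.48), with oncostatin M (Osm, at least 6.15-fold) and Timp1 (6.09-fold) higher and Il6ra (4.38-fold) and Tgfb3 (3.03-fold) lower. Osm had adjusted p = 0.0831 after normexp, and Igf1r was 1.83-fold higher with the mean over its probes. Of 18 luminal epithelium markers, 2 rose and 5 fell (2 and 8 adjusted over the list alone, mean -0.29, camera adjusted p = 0.0874); the keratin Krt7 (5.55-fold) was among those that rose, and Rab25 and Spint1 fell by 1.58 each on the log2 scale. Of 12 myoepithelial markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone, mean -0.47, camera adjusted p = 0.143), with Krt17 2.83-fold higher and Krt5 (2.77-fold), the calponin Cnn1 (2.42-fold) and Lmod1 (2.39-fold) lower. Cnn1 did not pass with quantile normalization (adjusted p = 0.0509), cyclic loess (0.0537) or the replicate block (0.0535). Without E. coli replicate 1 or replicate 2, none of the falls in these 4 lists passed, and 1 prolactin, 2 involution, 2 luminal and 0 myoepithelial genes kept their rise in either case.

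In the proliferation and stromal lists some genes fell, while neutrophil (mean 6.27) and skeletal muscle (mean 2.47) markers rose in the same arrays. Of 22 proliferation genes, 0 rose and 11 fell (0 and 13 adjusted over the list alone, mean -0.77, camera adjusted p = 0.00119; adjusted p = 0.351 with an estimated correlation), including the mitotic cyclins Ccnb2 (3.62-fold), Ccna2 (3.39-fold) and Ccnb1 (3.09-fold) and topoisomerase Top2a (2.83-fold; adjusted p = 0.0544 after normexp). Of 18 fibroblast and matrix genes, 1 rose and 10 fell (1 and 12 adjusted over the list alone, mean -0.63, camera adjusted p = 0.00369; adjusted p = 0.408 with an estimated correlation): Postn fell 4.10-fold, Col6a2 2.48-fold and Mfap5 2.47-fold, and the growth factor receptor Pdgfra rose 3.50-fold. Of 14 adipocyte markers, 0 rose, 6 fell and 1 was saturated in both groups (0 and 8 adjusted over the list alone, mean -0.68, camera adjusted p = 0.00498; adjusted p = 0.351 with an estimated correlation), among them Pck1 (3.08-fold), leptin (Lep, 2.60-fold), Cidec (2.23-fold) and adiponectin (Adipoq, 2.15-fold). Of 14 endothelial markers, 0 rose and 4 fell (0 and 4 adjusted over the list alone, mean -0.60, camera adjusted p = 0.0117; adjusted p = 0.351 with an estimated correlation): the claudin Cldn5 (5.18-fold), Robo4 (2.16-fold), Vwf (1.72-fold) and Tie1 (1.70-fold). Of 17 tight junction genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone, mean -0.49, camera adjusted p = 0.0142; adjusted p = 0.34 with an estimated correlation), with Cldn1 7.12-fold higher and Cldn5, cingulin Cgn (2.98-fold) and Cldn8 (2.59-fold) lower. After normexp the fibroblast, endothelial and tight junction lists did not pass (adjusted p = 0.0525, 0.0782 and 0.11), nor did Vwf and Tie1 (adjusted p = 0.0982 and 0.172), and Ccna2 was 2.14-fold lower and Cldn1 3.55-fold higher; Cgn did not pass with median scaling (adjusted p = 0.057). Vwf also did not pass with quantile normalization (adjusted p = 0.0572), median scaling (0.0937), the percentile over probes above background on all arrays (0.0696), NONCODE transcripts left out (0.0503), cyclic loess (0.0893) or the replicate block (0.0822), nor Tie1 with median scaling (0.0623), that percentile (0.0559), cyclic loess (0.0536) or the block (0.0842). When E. coli replicate 1 was left out, 0 proliferation, 0 fibroblast, 0 adipocyte, 1 endothelial and 1 tight junction gene kept their fall, and when replicate 2 was, 0 of each list; Cldn1 kept its rise in either case, Pdgfra in neither.

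The means of the metabolic and reference lists lay within 0.3 of 0. Of 32 oxidative phosphorylation genes, 0 rose, 3 fell and 1 was saturated in both groups (0 and 0 adjusted over the list alone, mean -0.26, camera adjusted p = 0.00815; adjusted p = 0.351 with an estimated correlation), among them Ndufa1 (1.77-fold) and Ndufb9 (1.66-fold). The list median was -0.43, further from 0 than the mean. Its member Atp5o read 6.10 on PBS replicate 1, -0.28 on PBS replicate 2 and 5.70 and 5.68 on the E. coli arrays, which raises the mean. After normexp the list did not pass (adjusted p = 0.136), nor did Ndufa1 (adjusted p = 0.0644) or Ndufb9 (adjusted p = 0.0509). Neither gene passed with quantile normalization (adjusted p = 0.0535 and 0.0509), cyclic loess (0.0565 and 0.0719) or the replicate block (0.0708 and 0.089). For oxidative stress and metallothioneins the mean was 0.17 and the median -0.41 (camera adjusted p = 0.685), with 6 of 23 higher, 1 lower and 1 saturated in both groups (7 and 6 adjusted over the list alone). The cystine transporter Slc7a11 was at least 13.1-fold higher, Hif1a 4.04-fold and Gpx2 2.21-fold, and Gpx4 fell 2.42-fold with 1 PBS array saturated. After normexp Slc7a11 was 3.05-fold higher, under its bound. Of 18 reference genes, 2 rose, 1 fell and 2 were saturated in both groups (0 and 0 adjusted over the list alone, mean 0.09, camera adjusted p = 0.623): Pgk1 rose 2.58-fold with 1 E. coli array saturated, B2m 2.21-fold, and Eif3f fell 1.71-fold. Eif3f did not pass with quantile normalization or without PBS replicate 2 (adjusted p = 0.0505 in both), with the percentile over probes above background on all arrays (0.0512), cyclic loess (0.0708) or the replicate block (0.0893). With either E. coli array left out, 0 of the 3 falls in oxidative phosphorylation, 0 of the 3 calls among reference genes, and 1 rise and 0 falls among oxidative stress genes were kept.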

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

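Leaving out NONCODE transcripts and cyclic loess were chosen after the data were seen; the other alternatives were fixed before. The main count of 7570 calls (3766 higher, 3804 lower, 5749 at 2-fold) lay within 1.5 times under quantile normalization, both other scalings, saturated probes out, probe means, every probe counted, the trended and robust variance, the stricter filter, the deposited log2 table, NONCODE out and cyclic loess. With normexp, 2492 genes were higher and 3639 changed at least 2-fold. Without a filter on dim probes, 123 genes passed (113 higher, 10 lower, 123 at 2-fold) of 49656 tested, with a prior of 1.69 degrees of freedom; the cause was not tested. At an adjusted p of 0.01, a stricter threshold by construction, 1991 passed (1348 higher, 643 lower, 1991 at 2-fold). With 1 array left out, the count ranged from 926 to 13544, the higher genes from 712 to 6163, the lower genes from 214 to 7381, and the 2-fold count from 926 to 8325. The lone array of a group is then assumed to vary like the other pair, with 1 residual degree of freedom: the low counts leave only the PBS pair to set the spread (median SD 0.236) and the high counts only the E. coli pair (0.107). Of the 187 named genes that passed, 139 lost their call without the filter on dim probes, 82 without E. coli replicate 1, 85 without E. coli replicate 2, 0 without PBS replicate 1, 1 without PBS replicate 2, 20 with normexp, 11 with the replicate block, 8 with cyclic loess and 7 with quantile normalization. The median change of all genes was -0.10, against -0.21 with normexp, 0.00504 with the 75th percentile over probes above background on all arrays and 0.05 with cyclic loess. By over 1.5-fold, 81 of the 187 moved toward 0 with normexp and 8 with the mean over a gene's probes, 1 moved away with quantile normalization, and 13 moved without PBS replicate 1 and 13 without PBS replicate 2. The offset of normexp pulls the changes of dim genes toward 0 by construction. None of the named genes that passed turned direction in any setting. Among all calls, 2 turned, with the mean over probes.

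With the replicate number as a block, 6100 genes passed, 5682 of them shared with the main calls. Deviations of same-numbered arrays from their group means correlated at r = -0.00639 across genes, so the arrays share only a number, and the block changed no list's call.

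The number of lists that passed was 26, between 22 (normexp) and 27 (no filter) over the array settings, 30 with fry and 0 with an estimated correlation (lowest adjusted p = 0.206). Lymph node stroma passed with normexp (adjusted p = 0.0413), without the filter (0.0409) and with fry; fry also called the lactose, luminal and myoepithelial lists. Among named genes and lists, the values that changed sign belonged to those that had not passed, and the cause was not tested. Dendritic cells and MHC class II moved from 0.19 to -0.081 with normexp, -0.00946 without the filter and -0.11 with the stricter filter, where oxidative stress was -0.093. Involution was 0.029 with quantile normalization and with the percentile over probes above background, 0.00945 without saturated probes, 0.0117 with NONCODE out and 0.11 with cyclic loess, and -0.25 to 0.098 with arrays left out in turn. Cholesterol synthesis was 0.060 with that percentile, 0.061 without saturated probes, 0.0067 with probe means, 0.042 with NONCODE out, 0.13 with cyclic loess, and -0.23 to 0.13 with arrays left out. Its member Pmvk read 3.54 on PBS replicate 1, 7.83 on PBS replicate 2 and 2.95 and 2.84 on the E. coli arrays, which lowers the main mean. Lactose was 0.026 with the percentile over probes above background, 0.00819 with NONCODE out and 0.088 with cyclic loess, where prolactin was 0.058. With arrays left out, reference genes ranged from -0.0054 (without PBS replicate 1) to 0.18, Cd14 from -0.42 to 0.0019 (without E. coli replicate 1) and Wap from -0.73 to 0.045 (without PBS replicate 2). Both genes are saturated in both groups, so neither a fold nor a sign can be read from these differences. Signal over background limits the genes dim on both PBS arrays, whose folds are bounds only. It also limits those above background on a single PBS array, whose printed folds rest in part on a dim value. Saturation limits the brightest milk and acute phase genes.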

Other observations

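The comparison of luminal with milk protein genes was chosen after the result was seen, as were the gene families described next; the other tests of explanations were fixed before their results. Genes were grouped by the stem of their symbol into 257 families with at least 8 tested members. At the preset correlation, 17 passed camera toward higher and 11 toward lower. With an estimated correlation none passed (lowest camera adjusted p = 0.854), and 6 were at an unadjusted p under 0.05. That version had little power with 2 residual degrees of freedom. Among families that the lists above cover only in part, all 10 guanylate-binding proteins (Gbp), which attack pathogens inside cells, rose (mean 2.94, adjusted p = 5.08e-07), as did 9 of 10 Ms4a genes (mean 3.48, adjusted p = 1.63e-07) and 7 of 8 Schlafen genes (Slfn, mean 4.36, adjusted p = 2.2e-05). Of 24 C-type lectin genes (Clec), 14 rose and 3 fell (mean 2.28, adjusted p = 0.000187). The serine protease inhibitors of the Serpina family (8 of 11 higher, mean 1.78, camera adjusted p = 0.000125) were also higher. So were the major urinary proteins (Mup, 7 of 8 higher, mean 1.88, camera adjusted p = 8.16e-05). Whether the probes of these 2 families read more than 1 member was not tested. The members of every family passed the filter on dim probes, which may raise a family's mean, as described for vomeronasal receptors below. For the families named here, means without the filter were not computed.

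Of 13 immunoglobulin kappa variable segments (Igkv), 12 fell and 0 rose (mean -1.48, adjusted p = 3.74e-05; adjusted p = 0.854 with an estimated correlation), and the gamma heavy chain Ighg fell by 2.75 ± 0.16 (adjusted p = 0.00306) and the mu heavy chain Ighm by 1.11 ± 0.28 (adjusted p = 0.0494), the heavy chains being chosen after their values were seen. In the same arrays the plasma cell genes Tnfrsf17 and Jchain fell and the B cell surface genes Ms4a1 and Cd22 rose. Lower families also included the coenzyme Q synthesis genes (Coq, 6 of 10 lower, mean -0.95, adjusted p = 0.00949) and the N-acetyltransferases (Nat, 7 of 11 lower, mean -1.07, adjusted p = 0.0255). The PBS arrays differed from each other more than 4-fold in 533 genes and the E. coli arrays in 127.

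Skeletal muscle transcripts were higher in both E. coli arrays. A dimmer PBS replicate 2 as the cause is argued against, since the list mean without that array was 2.45 (adjusted p = 1.11e-07 at the preset correlation; with all arrays and an estimated correlation the list had adjusted p = 0.206). More muscle tissue in the E. coli samples may account for it: of 57 further muscle genes listed before their values were looked at, 48 were tested, with a median change of 2.39, 41 higher (85.4%), 39 called higher and 4 called lower, and none of these or of the 15 listed markers is in another list. The abundant Acta1 went from 2.48 to 5.24 and Tnnc2 from 3.72 to 6.51 on the scaled log2 axis, although all 15 markers were already above background with PBS, and Mb, Casq2, Fbp2, Tpm1 and Ldb3 fell, which more muscle alone leaves unaccounted for. Whether dissection or the infection itself brought more muscle RNA was not tested.

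Some milk protein genes (8 of 17) and milk lipid genes (13 of 30) were called lower after E. coli, and the means of both lists were below 0. A dimmer PBS replicate 2 is argued against as the cause, since without it the list means were -0.89 (adjusted p = 0.00439) and -0.84 (adjusted p = 6.32e-06) at the preset correlation. With all arrays and an estimated correlation the lists did not pass (adjusted p = 0.351 and 0.257). A smaller share of epithelial cells, if all kinds were lost alike, would lower epithelial markers as far as milk protein genes. Of 15 luminal markers with no saturated array, 11 had a 95% interval wholly above the median of the 7 unsaturated milk protein genes (-1.69, luminal median -0.64). For those 7 genes this argues against an equal loss of all kinds as the whole cause. That median was given no interval, however, and over all members, saturated ones included, the medians were -0.67 and -0.56. A loss of milk-secreting cells alone cannot be told apart by this comparison. For milk lipid genes (median -0.78) a smaller share of epithelial cells was not tested and stays open. A rise of luminal markers within the remaining cells, which would hide a loss of epithelial cells, stays open. An effect of the infection on milk gene transcription stays open as well and was not tested separately.

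Probes for vomeronasal receptors, which serve the sense of smell, appeared among the higher families (45 genes, mean 1.02, median 1.19). This may come from the filter on dim probes, which lets a gene in when it is bright in a single group: 5 of the 45 were above background on all arrays and 21 on no PBS array, and without the filter the mean over all 334 such genes was -0.13, against -0.23 over all genes. The mean of the 45 without PBS replicate 2 was 1.08, so the dimness of that array by itself was not shown to be the reason. No biological explanation was tested.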
